A study of Mus musculus with 3 samples.

How the data were processed

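The study measured messenger RNA of SKOM-infected mouse embryonic fibroblasts on Affymetrix Mouse Genome 430 2.0 arrays, 1-colour arrays on which a transcript is read by a set of short probes. Per the labels' protocols, the feeder cells were removed, RNA was extracted with Trizol and biotin-labelled cRNA was hybridised. The 3 arrays are Control, SKOM+Tgfb1 and SKOM+Snail, 1 each, grouped by the labels. The authors deposited log2 signals, and RMA (background correction, quantile normalization and median polish over probes) is named in the submitters' processing notes, with no version. Which other arrays, if any, were normalized together with these 3 is not given in the sources used here. Many values were equal between arrays. Of the 45101 probe sets, 8960 (19.9%) had the same value on all 3 arrays and 45.6% on at least 2, so a difference of exactly 0 does not show that a transcript did not differ.

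The deposited log2 values were used as they stand, and a difference is the log2 value of one array minus that of another. Folds are 2 to the power of that difference. Gene names came from the platform's annotation table, which can be old. It gives 1 gene for 34958 probe sets and several for 932, and 9160 were not listed and stay unnamed here. Of 64 control probe sets, 13 are listed with a gene and count among those with 1, and 51 are not listed. Among the 34958, Entrez identifiers matched the RefSeq gene table of GRCm38.p6 for 34754, and 0 symbols were updated. Of the unlisted probe sets, 92 were past 2-fold in SKOM+Tgfb1 against Control, 42 in SKOM+Snail against Control and 113 between the 2 treated arrays. A gene was represented by its probe set with the highest mean over the arrays among those that name 1 gene. It was counted where its highest signal was at or above the pooled median of 5.33, which left 11595 of 18194 genes. No coordinates are given, since no genome sequence was used here.

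Because each group has 1 array, no test was run. Counts are of genes at least 2-fold higher or lower, and of list members at least 1.5-fold higher or lower. For a gene list, the median log2 difference of its counted members was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and its percentile describes these arrays only. The interval of a median is the 95% binomial order-statistic interval over the list's genes and covers the spread between genes, not between cultures. Lists with fewer than 5 counted genes have no percentile. The overlap of the differences from Control was set against independent lists and against 100 simulations of 3 unchanged arrays sharing 1 control, with a noise of 0.15 log2 units taken from the spread between the Snail-labelled and Control arrays for want of replicates, and against 100 draws in which each gene's values were exchanged among the arrays.

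The comparisons, 27 gene lists, 9 lists of cell type markers, the rule for named genes and all alternatives but 1 were fixed before the data were examined. Named for each comparison with Control were Snai1, Tgfb1, Cdh1 and the reprogramming factors, and the 10 largest differences each way among counted genes whose counted probe sets all differed in the same direction. Up to 4 members with the largest differences were named for each list described. Between the treated arrays the 6 largest each way were named, and for genes past 2-fold in both comparisons the 5 with the largest smaller difference each way, and up to 5 opposite ones. The lists cover epithelial junctions and keratins, epithelial regulators and proteases, mesenchymal regulators, extracellular matrix, TGF-beta induced genes, contractile cytoskeleton, BMP and Id response, pluripotency, germline, reprogramming factors, cell cycle, growth arrest and p53, interferon, chemokines, matrix proteases, hypoxia and glycolysis, cholesterol synthesis, amino acid and ER stress, immediate early genes, Wnt, Notch, imprinted genes, ribosomal proteins, oxidative phosphorylation, Hox genes, reference genes and sex-linked genes. The marker lists cover leukocytes, endothelium, keratinocytes, neural cells, skeletal muscle, adipocytes, cartilage and bone, extraembryonic endoderm and trophoblast. Some genes stand in more than 1 list.

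The alternatives were centring each array on its median, quantile normalization of the 3 arrays, no filter, a filter at the pooled 75th percentile (7.59), the mean of a gene's probe sets, leaving out probe sets ending in _s_at or _x_at, adding 32 on the linear scale before log2, and 1.5-fold or 4-fold as the size. An alternative without list members whose values were equal on at least 2 arrays was chosen after seeing the data. The counting steps were tested on simulated data for SKOM+Tgfb1 against Control with a noise of 0.15 log2 units over 11595 genes. Of 50 simulated genes each at 2.5-fold, 4-fold and 8-fold, 100% were counted past 2-fold in the right direction, and of 50 at 1.5-fold 2% were. Of 11395 simulated unchanged genes 0 were counted. Noise of this size rarely reaches 2-fold, so that 0 does not estimate false counts on the real arrays. Of 100 unchanged lists of 25 genes 7 fell outside the central 95% of random lists, and 20 of 20 lists shifted by 0.5 lay above the 97.5th percentile. The 51 unlisted control probe sets were left out of the comparisons. The 13 listed ones were treated like other probe sets of their genes, and 1 of them, for Gapdh, represents its gene. A further test, set before its result was seen, is not reported here. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.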

Results

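Mouse embryonic fibroblasts from OG2 mice were infected with retroviruses carrying Sox2, Klf4, Oct4 and c-Myc (SKOM), the factor set used to turn fibroblasts into induced pluripotent stem cells, and were then kept in mouse embryonic stem cell medium. RNA was profiled on day 10 in 3 groups. Control cells received the 4 factors alone. SKOM+Tgfb1 cells also received the growth factor Tgfb1 at 2 ng/ml from day 3 to day 10. SKOM+Snail is the label of cells described as co-expressing Snail, the protein of the Snai1 gene and a repressor of E-cadherin (Cdh1) known from the epithelial to mesenchymal transition. The comparisons ask how expression at this point of reprogramming differed in the groups labelled with an inducer of that transition. Each group had 1 array, so the differences below have no replicate check and no p-value, and the number of arrays limits their precision. The arrays gave deposited log2 RMA signals for 45101 probe sets, with medians of 5.36 in Control, 5.32 in SKOM+Tgfb1 and 5.33 in SKOM+Snail. The genes counted were 11595 of 18194 genes with a probe set of their own. A counted gene can still be dim on 1 of the arrays compared. Where that signal lay below the pooled median of 5.33 it was not shown to be above background, and the size and rank of the fold are uncertain.

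The perturbed genes were read first. Snai1 had a log2 signal of 6.61 in Control, 7.55 in SKOM+Tgfb1 and 6.04 in SKOM+Snail, so it was 1.93-fold higher with Tgfb1 but 1.48-fold lower in the array labelled SKOM+Snail. If this probe set reads the transduced Snail, its signal goes against that label. The array is called the Snail-labelled array from here on. Where the probes lie in the transcript was not examined, so whether they read the transduced Snail is open. The Tgfb1 transcript was 5.87-fold higher in SKOM+Tgfb1 than in Control and 1.15-fold higher in the Snail-labelled array. Of the 4 reprogramming factors, 3 were counted. Oct4 (Pou5f1) was 1.38-fold lower with Tgfb1 and 1.56-fold lower in the Snail-labelled array, and c-Myc (Myc) differed by 1.01-fold in each. Klf4 was 1.32-fold lower with Tgfb1 on its brighter probe set but 2.10-fold higher on a dimmer probe set, and 1.28-fold and 1.13-fold lower on these in the Snail-labelled array. Sox2 stayed below the level for counting on all arrays, at 3.88, 3.84 and 3.84.

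**Figure D1:**
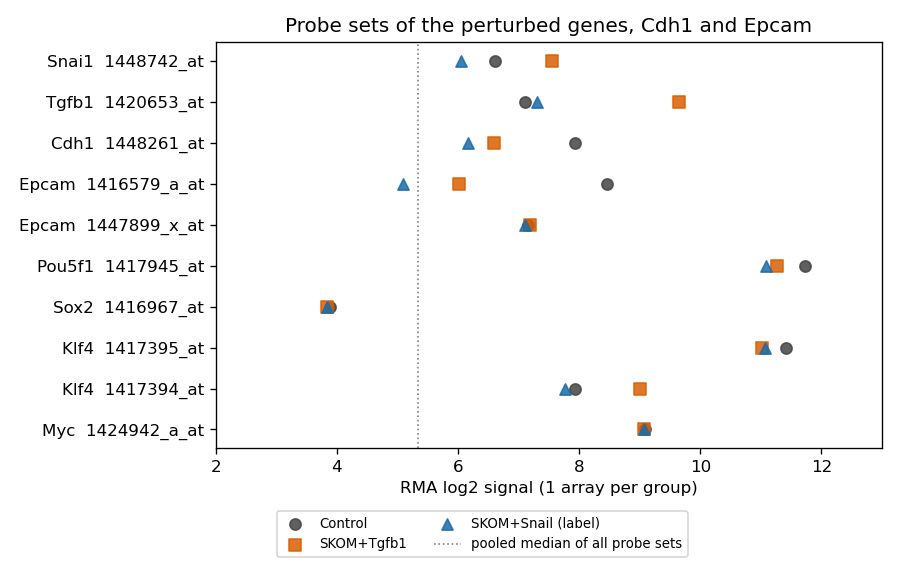
Log2 RMA signal (horizontal axis) of 10 probe sets (vertical axis) of the perturbed genes, Cdh1 and Epcam on the 3 arrays, each point 1 array, with the pooled median of all probe sets as a dotted line. Snai1 is lowest in the Snail-labelled array (6.04), and the 2 Epcam probe sets differ in behaviour, with 8.46, 6.02 and 5.09 on the first and 7.16, 7.18 and 7.11 on the second.

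With Tgfb1, known targets of the TGF-beta pathway and genes of the contractile cytoskeleton were higher than in Control, and cell cycle genes were lower. Of 26 counted TGF-beta induced genes, 18 were at least 1.5-fold higher and 0 lower. They included the NADPH oxidase Nox4 (11-fold), the pathway inhibitor Pmepa1 (6.22-fold), the EGF receptor ligand Hbegf (5.73-fold) and the activin subunit gene Inhba (5.50-fold). The Nox4 signal in Control (5.21) was below the pooled median, so its fold is uncertain in size. Of 22 contractile genes 16 were higher and 1 lower, with calponin Cnn1 5.47-fold, Pdlim7 4.05-fold, Tagln 3.35-fold and Zyx 2.69-fold higher. Of 30 cell cycle genes 27 were lower and 0 higher, among them Nusap1 (3.18-fold), the proliferation marker Mki67 (3.15-fold), the mitotic kinesin Kif11 (2.80-fold) and the replication helicase subunit Mcm5 (2.61-fold). The list medians were 0.99 (95% interval over the list's genes 0.56 to 1.95), 0.85 (0.48 to 1.14) and −1.06 (−1.23 to −0.83) on the log2 scale. The TGF-beta and contractile medians lay above all of 10000 random lists matched on expression, and the cell cycle median below all of them.

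More epithelial genes were lower than higher with Tgfb1, and some did not differ. Of 21 counted genes of epithelial junctions and keratins, 8 were at least 1.5-fold lower and 2 higher, with a median of −0.20 (−1.05 to 0.14) at percentile 0.86 of random lists. With a stricter filter on low signals, which left fewer members, 3 were lower and the direction turned, to a median of 0.06. With the mean of a gene's probe sets the median was −0.56. E-cadherin (Cdh1) was 2.55-fold lower, and the tight junction genes Cldn3 and Cldn4 were 2.37-fold and 2.29-fold lower, while plakoglobin (Jup) was 2.34-fold higher. The other higher member was the desmosomal Pkp2, at 1.51-fold, named here after its value was seen. Of 15 epithelial regulators and proteases, 10 were lower and 1 higher, with a median of −0.87 that lay below all random lists. The epithelial splicing regulator Esrp1 was 4.94-fold lower, the protease inhibitors Spint1 and Spint2 2.82-fold and 2.60-fold lower, and Grhl1 2.42-fold lower. In SKOM+Tgfb1 the signals of Esrp1 (4.18), Spint1 (4.43), Grhl1 (4.70) and Cldn4 (4.99) were below the pooled median. Their folds are uncertain in size. Epcam counted as a member without a difference, since its brighter probe set, of a type that can match several transcripts, differed by 1.02-fold. Its other probe set was 5.45-fold lower with Tgfb1 and 10.3-fold lower in the Snail-labelled array. Keratinocyte markers went both ways with Tgfb1. Of 12, 3 were higher, including Sfn (4.03-fold) and Krt14 (2.80-fold), and 4 lower, including Lgals7 (3.92-fold) and Sprr1a (3.43-fold).

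Matrix genes and part of the mesenchymal genes were higher with Tgfb1. Of 24 mesenchymal regulators and adhesion genes 8 were higher and 1 lower, with N-cadherin (Cdh2) 2.97-fold, Ncam1 2.39-fold, Pdgfrb 2.27-fold and Mmp14 1.98-fold higher. The median was 0.46, above all random lists, although its interval over genes reached below 0 (−0.10 to 0.64). Of 30 extracellular matrix genes 16 were higher, such as the crosslinking enzyme Lox (3.34-fold) and thrombospondin Thbs1 (2.64-fold). The 3 lower members included the small proteoglycans Lum (6.49-fold, from a dim SKOM+Tgfb1 signal of 4.57) and Dcn (3.12-fold). Among 16 matrix proteases and related genes 9 were higher and 0 lower, with Adamts4 3.70-fold, Adam19 2.98-fold, Ctsk 2.3-fold and Mmp11 2.20-fold higher.

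Pluripotency genes were lower with Tgfb1. Of 24 counted members 13 were at least 1.5-fold lower and 1 higher, with a median of −0.70 (−1.69 to 0.00) below all random lists. A stricter filter on low signals left fewer members, and all of them but Mkrn1 (5 genes) were at least 1.5-fold lower. Nr0b1, Mybl2 and Alpl reached that filter only in Control (8.22, 7.69 and 7.68), so passing it favours lower values. Among the 13 lower genes were Nr0b1 (8.40-fold), Nanog (6.46-fold), L1td1 (5.36-fold) and Fbxo15 (4.60-fold). In SKOM+Tgfb1 the signals of Nr0b1 (5.15), Nanog (4.60) and Fbxo15 (5.15) were below the pooled median, so their folds are uncertain in size. In the BMP and Id list 4 of 16 were lower, including Id2 (4.49-fold), Id4 (3.88-fold) and Bmp2 (3.40-fold), and 2 were higher, including Hey1 (1.99-fold), with a median at percentile 0.68. Interferon response genes were lower in 4 of 16, led by Gbp2 (3.25-fold), with a median of −0.38 at percentile 0.06. The SKOM+Tgfb1 signals of Bmp2 (4.52) and Gbp2 (4.87) were below the pooled median too. Genes of the amino acid and ER stress response were higher in 10 of 26, with Chac1 3.84-fold, Trib3 2.17-fold and Ddit3 2.01-fold higher, and lower in 0. The second Ddit3 probe set differed by only 0.07 on the log2 scale.

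The largest differences with Tgfb1 were found outside most of these lists. The chemokine receptor Cxcr6 was 19.5-fold higher than in Control, the melanin-concentrating hormone precursor Pmch 14.2-fold, the steroid synthesis enzyme Cyp11a1 14.1-fold, C1qtnf3 12.2-fold, the annexin Anxa10 11.6-fold, the acetylcholine receptor subunit Chrna7 10.7-fold, the claudin Cldn23 9.54-fold, the receptor phosphatase Ptprb 8.80-fold and Ankrd1 8.32-fold. The proton pump subunit Atp12a was 13.2-fold lower, Galnt15 9.86-fold, the water channel Aqp3 9.77-fold, Scara3 9.74-fold, the skin protein gene Dmkn 9.29-fold, the protein kinase C gene Prkcb 9.11-fold, Dmrtc2 9.05-fold, Nat8f3 9.01-fold, the adhesion molecule Chl1 8.91-fold and Lbp 8.71-fold. Of these genes Pmch, C1qtnf3, Ptprb, Aqp3, Scara3 and Lbp were above the pooled median on both arrays, and the folds of the others are uncertain in size. In all, 387 genes were at least 2-fold higher and 455 at least 2-fold lower, 7.26% of the genes counted. For genes past 2-fold with further probe sets, 98.3% of those 545 probe sets differed in the same direction. With 32 added before log2, 267 genes were 2-fold lower, and with a stricter filter on low signals 292 were. Of the genes past 2-fold, 24.5% were below the pooled median on the dimmer array.

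**Figure D2:**
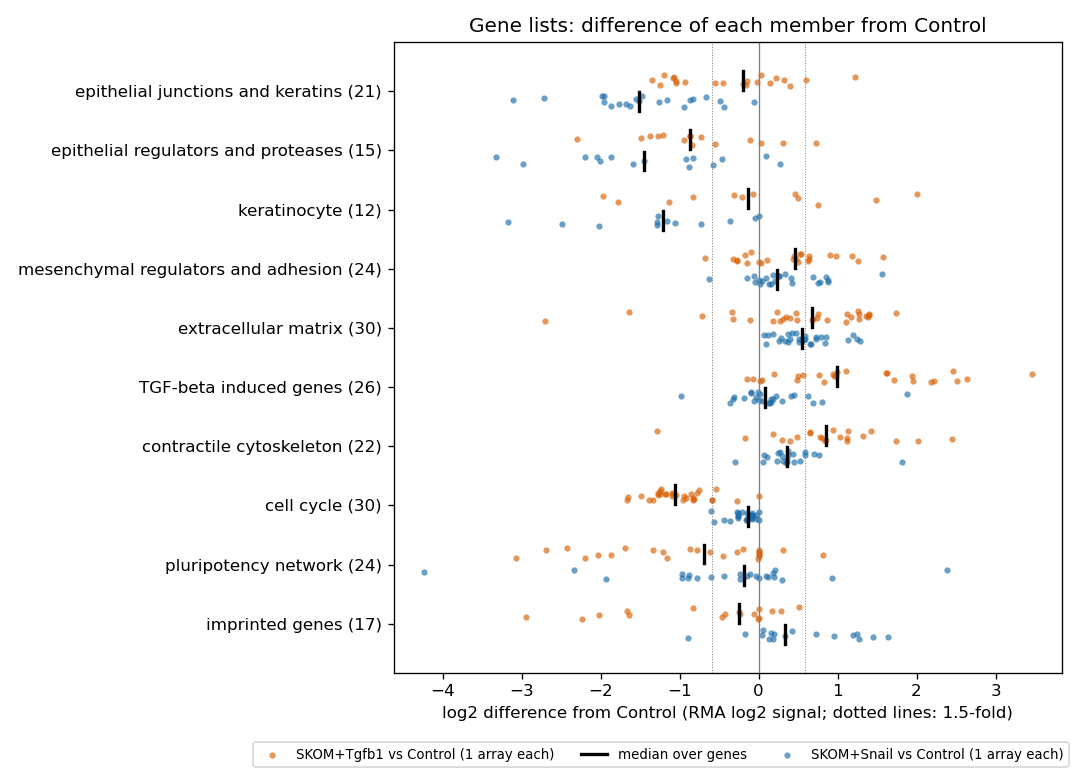
Log2 difference from Control (horizontal axis) of each counted member of 10 gene lists (vertical axis, number of members in brackets), orange for SKOM+Tgfb1 and blue for the Snail-labelled array, each point 1 gene from 1 array per group, with black bars at the medians over genes. Medians of the cell cycle list were −1.06 and −0.13, and those of the epithelial junction and keratin list −0.20 and −1.51.

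In the Snail-labelled array, epithelial genes were lower than in Control across nearly the whole list. Of the 21 counted genes of epithelial junctions and keratins 18 were at least 1.5-fold lower and 0 higher, with a median of −1.51 (−1.87 to −0.87), below all random lists. With 32 added before log2 the median was −0.85. A stricter filter on low signals left fewer members, all 8 of them at least 1.5-fold lower, with a median of −1.57. That filter takes a gene's highest signal, and Cdh1, Krt19, Jup and Pkp2 reached it only on the other arrays. The largest differences in this list were those of the desmosomal plakophilin Pkp2 (8.65-fold lower), the adhesion gene Mpzl2 (6.57-fold), desmoplakin Dsp (3.94-fold) and Cldn3 (3.90-fold). E-cadherin (Cdh1) was 3.40-fold lower. Of 15 epithelial regulators and proteases 11 were lower and 0 higher, with Esrp1 10.0-fold, Spint2 7.87-fold, the membrane protease St14 4.60-fold and Erbb3 4.13-fold lower. In the Snail-labelled array Pkp2 (4.09), Mpzl2 (4.48), Esrp1 (3.16) and St14 (4.90) were below the pooled median, so their folds are uncertain in size. Keratinocyte markers were lower in 9 of 12, led by the keratins Krt6b (9.0-fold) and Krt6a (5.61-fold), with Sprr1a (4.05-fold) and Krt14 (2.44-fold), and their median was −1.22. These directions hold for the array as labelled, in which the Snai1 signal was not higher.

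Matrix and mesenchymal genes were higher in the Snail-labelled array, by smaller steps. Of 30 extracellular matrix genes 12 were higher and 0 lower, with a median of 0.55 (0.39 to 0.66), and the leading members were Col11a1 (2.43-fold), elastin Eln (2.37-fold), Mfap5 (2.3-fold) and Fbln1 (2.20-fold). Another Fbln1 probe set differed by only 0.01 on the log2 scale. Of 24 mesenchymal genes 7 were higher and 1 lower, with Pdgfra 2.95-fold and Mmp2, Cdh11 and Zeb2 between 1.81-fold and 1.84-fold higher. Matrix proteases were higher in 7 of 16 and lower in 1, with Adamts5 1.96-fold and Adamts4 1.92-fold higher. Contractile genes had a median of 0.36 with 3 of 22 at least 1.5-fold higher, led by Pdlim3 (3.52-fold). The medians of these 4 lists lay above all random lists. TGF-beta induced genes were higher in 4 of 26 and lower in 1, with Tgfbi 3.68-fold higher and Hbegf 1.98-fold lower, and their median of 0.08 lay at percentile 96.2.

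Cell cycle genes were slightly lower in the Snail-labelled array than in Control. Of 30, 1 was past 1.5-fold, Rrm2 at 1.52-fold lower, and the median was −0.13 (−0.21 to −0.08), at percentile 0.16 of random lists. Pluripotency genes were lower in 9 of 24 and higher in 2, with a median of −0.19 (−0.88 to 0.13) at percentile 0.06. A stricter filter on low signals left fewer members, and all but Mkrn1 and Jarid2 (4 genes) were at least 1.5-fold lower. Here too, Nr0b1, Mybl2 and Alpl passed it through their Control signal alone. Nr0b1 was 18.8-fold lower, L1td1 5.07-fold and Nanog 3.81-fold, whereas the homeobox gene Otx2 was 5.23-fold higher. The BMP and Id list had 3 of 16 lower and 1 higher, including Gata2 (1.78-fold lower) and Bmp4 (1.53-fold higher). Interferon response genes were lower in 3 of 16, with Bst2 2.84-fold and Oas1a 2.04-fold lower and a median at percentile 0.38. Hypoxia and glycolysis genes had a median of −0.29, below all random lists, with the phosphofructokinase Pfkp 1.86-fold and the glucose transporter Slc2a1 1.73-fold lower, although only 3 of 23 were past 1.5-fold lower and 1 higher. The same list had a median of −0.08 at percentile 15 with Tgfb1. Amino acid and ER stress genes were higher in 2 of 26.

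The largest differences in the Snail-labelled array were on the lower side. Bex1 was 24.7-fold lower than in Control, Nr0b1 18.8-fold, the ubiquitin hydrolase Uchl1 18.3-fold, Fgfbp1 16.4-fold, Fxyd6 16.3-fold, Bex4 15.5-fold, the amino acid transporter Slc7a3 13.1-fold, mesothelin (Msln) 12.3-fold, the stem cell surface marker Prom1 11.7-fold and Esrp1 10.0-fold. On the higher side were bone sialoprotein (Ibsp, 9.31-fold), Itih5 (8.68-fold), Otx2 (5.23-fold), Sox18 (4.11-fold), the Hedgehog target Gli1 (3.75-fold), Nrcam (3.75-fold), Tgfbi (3.68-fold), Ppp1r3b (3.58-fold), chondromodulin (Cnmd, 3.52-fold) and Pdlim3 (3.52-fold). Signals below the pooled median stand behind the folds of Ibsp (2.97 in Control) and Otx2 (4.26 in Control), and behind those of Nr0b1 (3.99), Uchl1, Fgfbp1, Fxyd6, Bex4, Prom1 and Esrp1 (3.16) in the Snail-labelled array, so these are uncertain in size and rank. In all, 128 genes were at least 2-fold higher and 342 lower, 4.05% of those counted. At 4-fold the counts were 4 and 78. Of 271 further probe sets of these genes, 97.8% differed in the same direction. With 32 added before log2, 49 genes were 2-fold higher and 201 lower, and with a stricter filter on low signals 68 and 202. Of the genes past 2-fold, 29.4% were below the pooled median on the dimmer array.

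Set side by side without the shared Control, the Snail-labelled array (in which Snai1 was 2.85-fold lower than in SKOM+Tgfb1) had higher cell cycle genes than SKOM+Tgfb1 and lower TGF-beta induced and epithelial genes. Of 30 cell cycle genes 23 were at least 1.5-fold higher and 0 lower, with Mki67 3.09-fold and Kif11 2.54-fold higher. Of 26 TGF-beta induced genes 18 were lower and 1 higher, with Hbegf 11.3-fold and Nox4 6.79-fold lower. Of 21 epithelial junction and keratin genes 13 were lower and 0 higher, with a median of −0.69 (−1.63 to −0.41). Those with the largest gaps were the desmosomal genes Pkp2 (13.1-fold), Dsg2 (5.11-fold), Dsp (4.92-fold) and Jup (4.29-fold). Lum was 11.6-fold higher and Dcn 5.17-fold higher. Pluripotency genes were higher in 9 of 24 and lower in 3, with Otx2 11.7-fold and the DNA demethylase Tet1 7.0-fold higher and Nr0b1 2.24-fold lower. Across all genes, Cnmd (26.7-fold), Itih5 (21.7-fold), Scara3 (18.3-fold), the cell cycle inhibitor Cdkn1c (17.7-fold), Lbp (17.6-fold) and the Hedgehog antagonist Hhip (16.2-fold) were the highest relative to SKOM+Tgfb1. Msln (31.1-fold), Uchl1 (25.8-fold), Cxcr6 (23.8-fold), Anxa10 (22.3-fold), Cyp11a1 (18.8-fold) and Elmod1 (17.7-fold) were the lowest. The counts past 2-fold were 450 higher and 565 lower, 8.75% of genes, and 98.0% of 687 further probe sets went the same way. With a stricter filter on low signals they were 253 and 373, and with 32 added before log2 260 were higher. Of the genes past 2-fold, 27.9% were below the pooled median on the dimmer array, among them Otx2 (3.10 in SKOM+Tgfb1), Nr0b1 (3.99 in the Snail-labelled array), Tet1, Lum, Pkp2, Dsg2, Cnmd, Itih5, Hhip, Uchl1, Cxcr6, Anxa10, Cyp11a1 and Elmod1.

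Genes lower than Control in both arrays were more numerous than genes higher in both. At least 2-fold, 112 genes were lower in both and 12 higher in both, and 49 went in opposite directions. With 32 added before log2 these were 64, 4 and 17, with a stricter filter on low signals 59 were lower and 6 higher in both, and with the mean of a gene's probe sets 32 were opposite. Lower in both were Nr0b1, the transglutaminase Tgm3 (6.5-fold with Tgfb1 and 7.44-fold in the Snail-labelled array), Atp12a (13.2-fold and 6.34-fold), Dmkn (9.29-fold and 6.05-fold) and the receptor phosphatase Ptprz1 (7.77-fold and 5.96-fold). Higher in both were Chrna7 (10.7-fold and 3.22-fold), Frem1 (4.30-fold and 2.67-fold), Cotl1 (3.85-fold and 2.31-fold), Mfap5 (2.57-fold and 2.3-fold) and Gp1bb (3.60-fold and 2.28-fold). At least 1 other probe set each of Cotl1 and Gp1bb did not share these differences in the Snail-labelled array, with log2 values of −0.02 and 0.00. Opposite genes included Cnmd (7.57-fold lower and 3.52-fold higher), Hhip (4.84-fold lower and 3.35-fold higher), Srpx (3.18-fold lower and 3.41-fold higher) and Dlk1 (4.04-fold lower and 3.12-fold higher). Elmod1 went the other way, 5.58-fold higher with Tgfb1 and 3.18-fold lower in the Snail-labelled array.

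Independent lists of these sizes would share 13.4 lower genes, 4.27 higher genes and 16.4 opposite genes. Across genes, which are not independent replicates, Pearson's r of the differences was 0.20 and their covariance 0.049. With 3 simulated unchanged arrays sharing 1 control, r was 0.50, covariance 0.022 and the overlaps 0, at an assumed noise of 0.15 log2 units. Noise of that size rarely reaches 2-fold, so the overlaps of 0 follow from the setting. The r of 0.50 follows from it too, since equal noise on 3 arrays gives that value whatever its size. The Control array cannot be split, so part or all of the excess of genes lower or higher in both may come from it. With each gene's values exchanged at random among the 3 arrays, 161 genes on average were lower in both (136 to 181 in 100 draws), 137 higher in both (111 to 164) and 23.2 opposite (17 to 35). The observed 112 and 12 were below these ranges and the observed 49 above. These exchanges put differences of the treated arrays into the Control position, which by itself makes genes lower or higher in both. They do not picture unchanged arrays, so these gaps do not show that fewer genes were shared than by chance.

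**Figure D3:**
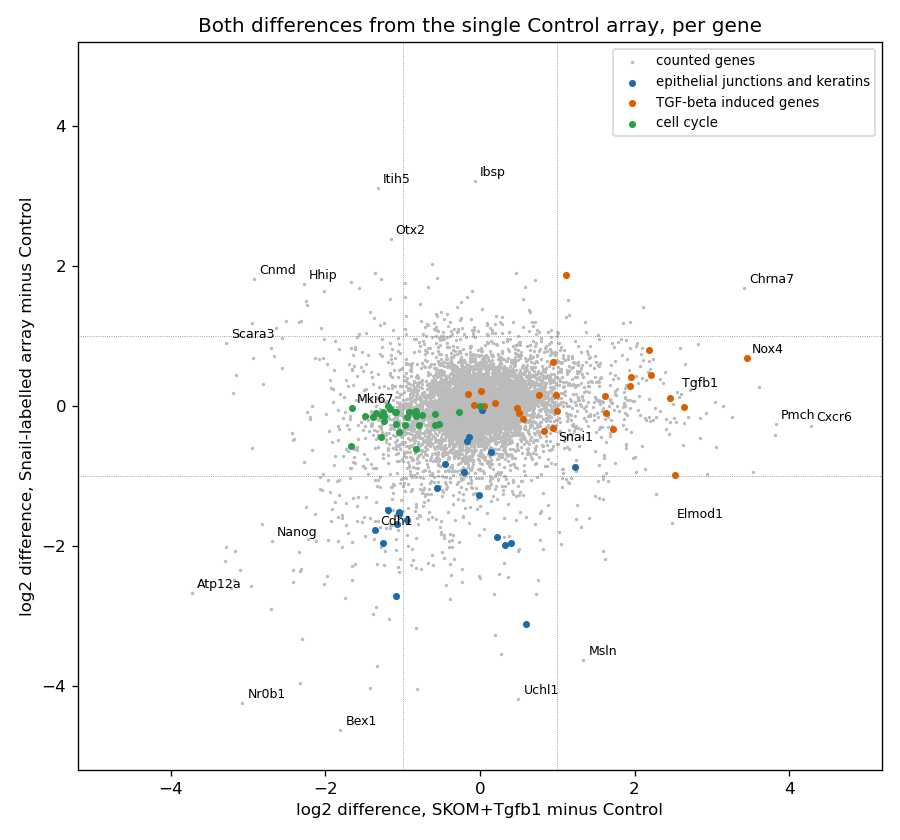
Log2 difference from the Control array for each counted gene, with SKOM+Tgfb1 on the horizontal and the Snail-labelled array on the vertical axis, 3 gene lists in colour and dotted lines at 2-fold. Each point is 1 gene, and the Control value enters both axes, with 112 genes at the lower left and 12 at the upper right past 2-fold.

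The remaining lists showed smaller or mixed differences from Control. Growth arrest and p53 genes had medians of −0.01 with Tgfb1 and −0.06 in the Snail-labelled array, with members such as Pmaip1 3.07-fold higher in the former and 4.56-fold lower in the latter. Chemokines and inflammatory genes split, with 5 higher and 7 lower of 20 with Tgfb1, where Il11 was 6.06-fold higher and Icam1 3.52-fold lower, and with 3 higher and 5 lower in the Snail-labelled array. Il11 in Control (4.88) and Icam1 in SKOM+Tgfb1 (3.72) were below the pooled median. Immediate early genes had medians of 0.13 (percentile 98.1) and −0.01, and Notch pathway genes 0.13 and 0.00, with Jag1 2.53-fold higher with Tgfb1, and Hey2 4.28-fold higher from a dim Control signal of 3.72. Cholesterol synthesis genes had medians of 0.04 and −0.12, the latter at percentile 1.16. Ribosomal protein genes (−0.04 and 0.01, 21 genes), oxidative phosphorylation genes (−0.10 and −0.08, 31 genes) and reference genes (−0.02 and 0.00, 14 genes) had small medians. The 31 oxidative phosphorylation genes included 0 past 1.5-fold, but their median in the Snail-labelled array lay at percentile 1.39. Of the reference genes Tfrc was 1.56-fold and 1.71-fold lower, and Gusb 1.56-fold higher with Tgfb1. In the germline and early embryo list only Prdm1 was counted, 2.16-fold lower in the Snail-labelled array and 1.22-fold lower with Tgfb1. The 4 counted sex-linked genes had medians of −0.08 and 0.12, with Xist 1.57-fold lower with Tgfb1.

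Markers of other cell types were mostly below the level for counting. Of 21 macrophage and leukocyte markers on the array 5 were counted, with medians of 0.02 and 0.00. Cd68 was 1.78-fold and 2.63-fold lower, and Laptm5 was 1.60-fold higher with Tgfb1. The 7 endothelial markers had medians of 0.07 and −0.02. With Tgfb1 1 was higher, Robo4 (3.22-fold), and 3 were lower, Tek (2.48-fold), Cldn5 (1.86-fold) and Sox18 (1.54-fold). In the Snail-labelled array Sox18 was 4.11-fold higher and Cldn5 1.98-fold lower. Of 8 skeletal muscle markers 3 were higher with Tgfb1, Chrna1 (8.21-fold), Tnnt2 (2.65-fold) and Acta1 (2.49-fold), and 1 lower, whereas in the Snail-labelled array 0 were higher and 2 lower. The median with Tgfb1, 0.29, lay at percentile 98.5. The 6 adipocyte markers had medians of −0.08 and −0.02, with Lpl 2.05-fold higher in the Snail-labelled array. The 9 extraembryonic endoderm markers had medians of 0.00 in both, with members going both ways. With Tgfb1 Lamb1 was 2.34-fold and Cubn 1.79-fold higher and Dab2 2.05-fold lower, and in the Snail-labelled array Pdgfra was 2.95-fold higher. Only 2 trophoblast markers were counted, with Tead4 1.80-fold lower in the Snail-labelled array. With 32 lists large enough for a percentile, 7 lay below and 11 above the central 95% of random lists with Tgfb1, and 10 below and 7 above in the Snail-labelled array, against 1.6 outside by chance if the genes of a list were independent.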

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

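All tests in this part were chosen after the results they bear on had been seen. Among the control probe sets that name no gene, which the comparisons leave out, some held signals above Control. The polyA spike-ins dap, lys, phe and thr, bacterial transcripts usually added to the RNA before labelling, were higher in all 24 probe sets, by a median of 0.15 log2 units in SKOM+Tgfb1 and 0.42 in the Snail-labelled array. The hybridisation spike-ins differed by medians of 0.05 and 0.00. The probe set for the murine B1 repeat was 0.52 log2 units higher in SKOM+Tgfb1 than in Control and differed from Control by −0.65 in the Snail-labelled array. The ratio of 3' to 5' signal was alike, at 0.35, 0.30 and 0.30 log2 units for beta-actin and −0.09, −0.09 and −0.11 for Gapdh in Control, SKOM+Tgfb1 and the Snail-labelled array.

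Snai1 was lower in the array labelled SKOM+Snail than in Control, and 3 explanations were set against the tables. An exchange of that array with Control would make epithelial genes higher in it. Their median was −1.51 log2 units with an interval that stays below 0, which argues against an exchange in so far as Snail lowers those genes. An exchange with SKOM+Tgfb1 would make TGF-beta induced genes higher than in SKOM+Tgfb1, and their median was −1.12, which argues against it. A candidate explanation that stays open is that the Snai1 probe set does not read the transduced Snail. The Sox2 probe set reached only 3.88 in cells transduced with Sox2, but a low level of the transduced RNA would look alike. Probe sets of the other transduced factors were bright in Control, with Pou5f1 at 11.73, Klf4 at 11.42 on its brighter probe set and Myc at 9.08. Whether these read the transduced RNA was not examined, so Sox2 alone says little about Snai1. A wrong label involving a sample outside the series or a failed Snail virus is not excluded either.

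Of the 21 epithelial junction and keratin genes, 8 were at least 1.5-fold lower than in Control with Tgfb1 and 18 in the Snail-labelled array, and a smaller share of epithelial cells was set against a change of expression within cells. The test counted list members at least 1.5-fold higher than Control, which a smaller share alone would not raise. There were 2 with Tgfb1, Jup (2.34-fold) and Pkp2 (1.51-fold), and 0 in the Snail-labelled array. Random lists matched on expression held 1.84 and 1.13 on average, with central 95% ranges of 0 to 5 and 0 to 3. No count can lie below 0, the lower end of both ranges, so the test could argue against a smaller share but never for one. The counts of 2 and 0 lay within the ranges, from 1 array per group, and did not argue against a smaller share. The random lists came from the same arrays, where 912 genes were at least 1.5-fold higher with Tgfb1. Their ranges therefore are not ranges of noise, and the test had little power against a smaller share. A smaller share of epithelial cells alone, with Tgfb1 or in the Snail-labelled array, and lower expression within cells are not told apart by this test. Either may hold, and the Tgfb1 treatment, and Snail if that label is right, stay open as untested biological causes.

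Identical values on all 3 arrays were found for 39.0% of the dimmest probe sets and 2.3% of the brightest, taken as the lowest and highest of 5 equal groups by mean signal. A low plateau of values would place nearly all of them below the pooled median, but 15.3% lay at or above it, which argues against a plateau as the whole cause. Median polish of 3 arrays may account for them. In simulated unchanged probe sets of 11 probes, 43.4% came out identical on 3 arrays. The simulation used the same signal level and noise throughout, so it does not address why dim probe sets were identical more often. The identical probe sets took only 733 distinct values, which the simulation does not address either. No biological explanation was tested for this pattern.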

How the results depend on the processing

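The alternative that left out list members with equal values was chosen after seeing the data, and it moved 0 medians. No paired analysis was possible because each group has 1 array, and leaving out replicates was not possible either. Counts are given as SKOM+Tgfb1 against Control, then the Snail-labelled array against Control, then between the treated arrays. Where the setting itself does not show it, the cause was not tested. At 1.5-fold, 912, 490 and 1122 genes were higher and 1082, 751 and 1181 lower, and at 4-fold 76, 4 and 82 were higher and 63, 78 and 139 lower. With the stricter filter, which tests fewer genes, 292, 202 and 373 were lower, 68 and 253 were higher in the latter 2 comparisons, and 6 were higher and 59 lower in both. Fewer list members stayed counted under that filter. Of these, 3 and 8 epithelial junction and keratin genes and 5 and 4 pluripotency genes were lower in SKOM+Tgfb1 and the Snail-labelled array. All epithelial members still counted were lower in the Snail-labelled array, with a median of −1.57. That filter uses a gene's highest signal, so it keeps genes that are bright only in Control. With 32 added before log2, which shrinks differences of dim probe sets, 267 and 201 genes were lower than in Control, 49 and 260 higher in the latter 2 comparisons, 4 higher and 64 lower in both and 17 opposite, and the epithelial median in the Snail-labelled array was −0.85. With the mean of a gene's probe sets, 32 genes were opposite. Without _s_at and _x_at probe sets Cotl1 in the Snail-labelled array reversed to −0.017. The other 116 counts stayed within 1.5 times. Of list medians 702 stayed within their intervals and 3 moved. Among lists outside the central 95% of random lists 1 median changed sign, that of the epithelial junctions and keratins with Tgfb1, at 0.06 with the stricter filter against −0.20, and it was −0.56 with the mean of probe sets and −0.50 without _s_at and _x_at probe sets. Lists within the central 95% gave the other sign changes, 23 in all with this. Of single gene values 3191 stayed within 1.5-fold and 159 moved. The filter settings cannot change a gene's value, and under centring and quantile normalization all 479 stayed, so the total says little about stability. Adding 32 before log2 moved 94, the mean of a gene's probe sets 55, and leaving out _s_at and _x_at probe sets 10. Centring shifted the arrays by −0.02, 0.02 and 0.01. No detection call was used, so how far signals near the pooled median of 5.33 stand above background is unknown, which limits what dim genes show.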

Other observations

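This part gives values of gene lists fixed before their values were seen, and no test was chosen after a result. Imprinted genes differed in direction between the arrays. Of 17 counted, 7 were at least 1.5-fold higher and 1 lower in the Snail-labelled array against Control (median 0.33, above all random lists), and 0 higher and 6 lower with Tgfb1 (median −0.24, percentile 0.41). The growth regulators Dlk1 (3.12-fold), Mest (2.74-fold), Peg3 (2.40-fold) and the noncoding Rian (2.37-fold) were higher in the Snail-labelled array, and Cdkn1c (7.72-fold), Mest (4.69-fold), Dlk1 (4.04-fold) and Nnat (3.18-fold) were lower with Tgfb1. Cartilage and bone markers were higher in 4 of 7 in the Snail-labelled array, Ibsp (9.31-fold, from a Control signal of only 2.97), Acan (2.67-fold), Sox9 (2.20-fold) and Sp7 (1.64-fold), and in 1 with Tgfb1, Col2a1 (2.06-fold). Their medians were 0.71 and −0.06. Wnt pathway genes had medians of 0.12 with Tgfb1, with 4 of 21 higher and 5 lower, and 0.20 in the Snail-labelled array, with 5 higher and 1 lower, at percentiles 98.3 and 99.9. Ccn4 and Wnt5a were 4.13-fold and 2.63-fold higher with Tgfb1. Sfrp2 and Wif1, which encode secreted Wnt antagonists, were 7.61-fold and 4.74-fold lower with Tgfb1, and 1.61-fold and 2.85-fold higher in the Snail-labelled array.

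Hox genes were higher in 6 of 21 with Tgfb1 and lower in 0 (median 0.36, above all random lists), led by Hoxa4 (5.51-fold), Hoxa3 (3.37-fold), Hoxc8 (2.07-fold) and Hoxa5 (1.91-fold). In the Snail-labelled array 0 were past 1.5-fold either way and the median was 0.07. Neural markers split with Tgfb1, with 4 higher and 3 lower of 11 and a median of 0.26 at percentile 99.1. The neuronal tubulin Tubb3 (3.95-fold), nestin (Nes, 3.72-fold), Fabp7 (3.69-fold) and Map2 (3.41-fold) were higher, and in the Snail-labelled array 0 were higher and 2 lower, with Nefl 2.59-fold and Tubb3 1.67-fold lower and a median of −0.27 at percentile 0.46.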
